A study of Mus musculus with 12 samples.

How the data were processed

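Cycloheximide, which stalls ribosomes, was injected into the tail vein shortly before death, and epidermal cells were freed with trypsin, per the labels' protocols. Live single cells were sorted into plates, the RNA left unprotected was digested, and small-RNA libraries were made of the remaining footprints. The deposited files give the count of footprint reads per gene for each well as whole numbers, with 22416 genes and 12 samples. Per the submitters' processing notes the authors used fastp, Bowtie2, STAR, UMI-tools and featureCounts with the build GRCm38.p6. Their versions, order and settings, the filter on wells and the positions within a transcript at which footprints were counted are not given in the sources used here. Reads of pseudogenes and near-identical copies may have been split or dropped in that step, which bears on ribosomal protein genes most. The instrument of each plate, where 2 kinds are named, is not given in the sources used here and was not used as a batch.

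Each sample is a plate. The design text gives 3 animals per age and calls plates technical replicates, and plates of the same age and postnatal day were taken as 1 animal, which is an assumption. It gave P758 2 plates, P662 2, P722 1, P60 3, P57 1 and P59 1. The replicate is the animal, and counts were summed over its wells. Over 20 pairs of plates of one age no 2 were identical. The lowest chi-square per degree of freedom was 1.47, and within an animal the values ran from 2.19 to 3.73, so that no plate repeated another within counting noise. The Sca-1-negative plate and the nuclease plate entered no test. Of the symbols, 21754 matched the reference table of the same build, from which coordinates come, and 662 did not. Of the genes in the fixed lists, 10 had no match in the files.

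A minimum of 500 counts per well was planned, with 100 in its place if an animal kept under 20 wells. At 500 counts P57 kept 4 wells, P59 3 and P722 7, so 100 was used. P57 still kept 13 wells, under that number, and stayed in. The median count per kept well was 219 in P662, 347 in P722, 865 in P758, 298 in P57, 168 in P59 and 1352 in P60. A single count is worth 191 CPM in P57 and 0.419 CPM in P60. Intervals are exact (Clopper-Pearson or Poisson) at 95% and, like floors of 3 counts, cover counting error only.

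The age test was edgeR 4.0.16 in R 4.3.3, with TMM factors (0.924 to 1.09), filterByExpr, robust quasi-likelihood fits and Benjamini-Hochberg adjustment at 0.05. The biological coefficient of variation was 0.308. Fold changes are log2 of old over young, and the SE is derived as the absolute log2 difference over the square root of the F statistic. DESeq2 1.42.0, limma-voom (limma 3.58.1) on plates with the animal as a random block (correlation 0.595), other filters, other minimum counts per well, thinning to 5230 counts per animal and leaving out each animal or plate were alternatives. Gene lists were tested with limma's camera on lists fixed before the data were examined, 21 by name and 2 by symbol (ribosomal protein and mitochondrially encoded genes). camera was also run with an estimated correlation, and fry beside it. Shares were compared with two-sided exact permutation tests in scipy 1.17.1. The test was run on simulated counts with the real means, depths and dispersions. Of the calls 7.14% were false at 2-fold, 2.06% at 4-fold and 6.10% at 8-fold changes. Changed genes that were called had the right direction in 100% of cases, and with no change 0 genes were called.

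Wells were clustered in scanpy 1.11.5 (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, igraph 0.11.9) on 1500 variable genes, centred per plate, with 15 components, 15 neighbours and Leiden resolution 1. Each well received 1 sorted cell and no doublet caller was run. A cluster was named for the marker list with the highest mean log2 ratio, if that was at least 0.25, at least 3 of its markers were higher in the cluster and its 10 leading genes held no more markers of another list. The marker lists were fixed before the data were examined, and the thresholds of the naming rule were set after the clusters were seen. Cluster 5, led by Krt79 and Krt17, scored 3.442 for the granular and 3.429 for the upper hair follicle list, and stayed unnamed because more of its leading genes were markers of the latter. A rule that counts leading markers first would have named it upper hair follicle-like, and it was tried and not used. Cluster 0, with 261 wells, was named basal-like at a score of 0.355, and none of its 10 leading genes was a basal marker. Cluster 1 reached the minimum for no list. Cluster 8, with a median of 297 counts per well, had under 3 markers of its best list higher. Figures were drawn with matplotlib 3.10.9.

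Genes were named by a rule fixed before the data were examined. It takes up to 10 called genes with the largest rise and 10 with the largest fall among those of at least 20 CPM without overlap between the ages. With fewer than 5 such genes, the 5 with the smallest p are named as not passing. Up to 4 members of each called list are named, and 12 fixed genes always. The other called genes of differentiated-like cells, H2-D1, the genes named for the interaction and those of the P758 and P60 comparison were chosen after their values were seen. For the last, genes needed 50 counts over both animals and plates without overlap, and the 10 largest ratios per direction were listed, of which 1 is not reported here. The medians of lists there, and on the Sca-1-negative plate, are set against 10000 random lists matched on level.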

Results

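Ribosome footprints, the stretches of mRNA that a ribosome shields from nuclease, were counted per gene in single epidermal cells from the back skin of young and old female C57BL/6 mice. The young animals are called P57, P59 and P60 and the old ones P662, P722 and P758 after their postnatal days (n = 3 per age). The 10 plates filled without a Sca-1 gate held 1924 wells, of which 1906 had at least 100 counts and were kept. The summed count was 5230 in P57 from 13 wells, 12371 in P59 from 48 wells and 2384294 in P60 from 981 wells. Among old animals it was 70549 in P662 from 199 wells, 12886 in P722 from 38 wells and 896688 in P758 from 627 wells. Another plate held Sca-1-negative cells and another a test of nucleases. No matched mRNA counts were used, so each value joins the abundance of an mRNA with its translation.

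The question of the design was how translation in the epidermis differs with age. Across all wells, Cxcl14, a chemokine of the skin, had 187 ± 53.8 CPM in old and 357 ± 185 CPM in young animals (SD, n = 3 each), a fitted log2 difference of -1.16 (SE 0.334). Dmkn, which codes for dermokine of the suprabasal layers, had 1622 ± 313 CPM in old and 956 ± 174 CPM in young animals, a log2 difference of 0.89 (SE 0.295). Without P758 the log2 difference of Dmkn was 0.50. Its values did not overlap between the ages, and neither did those of Reep5, a membrane-shaping protein of the endoplasmic reticulum, at 205 ± 42.9 against 364 ± 35.4 CPM. For a single gene 3 against 3 values part in this way by chance in 10% of cases. Dsg1b, a desmosomal cadherin, had a fitted log2 difference of 0.95 and Ccnl1, a cyclin tied to splicing, one of 1.83. These 5 genes had the smallest p-values and none passed the test. edgeR's quasi-likelihood test called 0 of the tested genes, with a lowest adjusted p of 0.998 and 25 genes at an unadjusted p under 0.05, and DESeq2 called 0, with 10. The filter on low counts left only a small part of the genes in the files to be tested. These results and the simulation that follows cover those genes alone and do not speak for the others. Simulated 2-fold changes in 200 of the tested genes were recovered in 13% of cases and 4-fold changes in 95%. Without a filter on low counts the same test called 111 genes, and with a mean of at least 20 CPM it called 45. None of the 111 was among the genes of the filtered test. In GRCm38, Cxcl14 lies on chromosome 13 from 56288643 to 56296811 and Dmkn on chromosome 7 from 30763756 to 30781066.

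No called difference between the ages was found for keratins of the epidermal layers. Krt14, the keratin partner of Krt5 in the basal layer, had 8853 ± 3245 CPM in old and 7295 ± 5152 CPM in young animals (SD, n = 3). Krt5 had 18044 ± 9093 against 14960 ± 9319 CPM. The suprabasal keratins Krt1 and Krt10 had 14361 ± 2105 and 23550 ± 7211 CPM in old animals, beside 10499 ± 5532 and 20286 ± 10417 CPM in young ones. Krt15, a keratin of basal and bulge cells, had 8544 ± 4734 against 11438 ± 5265 CPM. Col17a1, a hemidesmosomal collagen, had 5985 ± 1091 against 4968 ± 2385 CPM. None of these passed the edgeR test, each with an adjusted p of 0.998. Ly6a, which codes for Sca-1, was too low to be tested, at 205 ± 168 against 75.0 ± 72.3 CPM. The cell cycle inhibitor Cdkn1a, also untested, had 153 ± 69.0 against 287 ± 249 CPM. Cdkn2a, a marker of senescence, had 4 counts over all 6 animals, too few to compare.

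Of 20 gene lists with at least 3 tested members, camera at a preset correlation of 0.01 called 3. The nuclear-encoded oxidative phosphorylation list, with 5 of its 74 genes tested, fell as a group. Its camera adjusted p was 0.00294, and 0.353 with an estimated correlation. All 5 tested members were lower in old animals, with a median log2 difference of -0.54. They included the ATP synthase subunits Atp5b at -0.81 and Atp5a1 at -0.54, Cox4i1 of cytochrome oxidase at -0.49 and Uqcrc1 of complex III at -0.54. Over all 74 genes the shares of counts overlapped between the ages. They were 0.561, 0.745 and 0.672% in P662, P722 and P758, beside 1.11, 0.719 and 0.843% in P57, P59 and P60. The list of histones and cell cycle genes fell (adjusted p = 0.00688, and adjusted p = 0.501 with an estimated correlation). Of its 20 genes in the files 3 were tested. They were the proliferation marker Mki67 at -1.45, the tubulin Tubb5 at -1.03 and the cyclin Ccnd2 at -0.35, so that no histone was among them. AP-1 and immediate early genes, which cells switch on within minutes of a stimulus, rose as a list (adjusted p = 0.00790, and adjusted p = 0.751 with an estimated correlation). All 16 tested members were positive, with a median of 0.81 and with Ier2 at 1.66, Egr2 at 1.78, Ccn1 at 1.27 and Klf6 at 0.80. No single member of these lists passed over all genes. Adjusted over the list alone, 2 cell cycle genes, 0 oxidative phosphorylation genes and 0 AP-1 genes passed. No list was called with an estimated correlation or by fry, and camera called 1 of 20 lists in a simulation with no change. Without P57 camera called 5 lists. Without P662, P758 or P60 only 8 lists had enough tested genes, and 0, 1 and 0 were called, the 1 being antigen presentation. The oxidative phosphorylation and cell cycle lists were not tested there. Without P722, P57 or P59 they passed, with an adjusted p of 0.00332 to 0.0335 and of 0.00166 to 0.0114. Without P662, P758, P57 or P60 the AP-1 list had an adjusted p of 0.968, 0.269, 0.0757 and 0.633, and without P722 or P59 one of 1.63e-09 and 2.01e-12.

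The other 17 lists had an adjusted p between 0.120 and 0.965 and none was called. They were antigen presentation, desmosome and adherens junction, the integrated stress and unfolded protein response, mitochondrially encoded proteins, antioxidant and metallothionein genes, keratins, hair follicle and epidermal transcription factors, and cytosolic ribosomal proteins. The remainder were the cornified envelope, secreted and extracellular matrix genes, lipid and cholesterol synthesis, cytokines and alarmins, heat shock genes and chaperones, hemidesmosome and basement membrane, translation factors, Notch and Wnt, and glycolysis. The median and the direction of the test differed in sign for lipid and cholesterol synthesis, heat shock genes, hemidesmosome genes and the Notch and Wnt list. Among cytokines, Cxcl14 alone passed when adjusted over the list alone. In antigen presentation the class I heavy chain H2-D1 had 901 ± 146 CPM in old and 1699 ± 261 CPM in young animals (SD, n = 3), without passing. The senescence and p53 list had 1 tested member, Igfbp3, at a fitted log2 difference of -0.54, although its plain means were 606 CPM in old and 478 CPM in young animals. It did not pass, and no gene of the interferon and proteasome lists was tested.

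AP-1 and immediate early genes took between 0.268% and 2.94% of an animal's counts. The share was 2.94% (95% binomial interval 2.81 to 3.06) in old P662, 1.53% (1.503 to 1.554) in old P758 and 0.551% (0.431 to 0.694) in old P722. In young animals it was 2.55% (2.28 to 2.85) in P59, 0.529% (0.520 to 0.539) in P60 and 0.268% (0.146 to 0.449) in P57. The means were 1.67 ± 1.20% in old and 1.12 ± 1.25% in young animals (SD, n = 3 each), with a two-sided exact permutation p of 0.5, where 0.1 is the smallest possible. Fos, a subunit of AP-1, ranged from 191 CPM in P57 to 2991 CPM in P59 among young animals, and from 543 CPM in P722 to 3898 CPM in P662 among old ones. Its partners Jun and Junb had 1597 ± 1262 and 1619 ± 762 CPM in old animals, beside 815 ± 1007 and 901 ± 1200 CPM in young ones. The intervals cover counting error only.

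**Figure D1:**
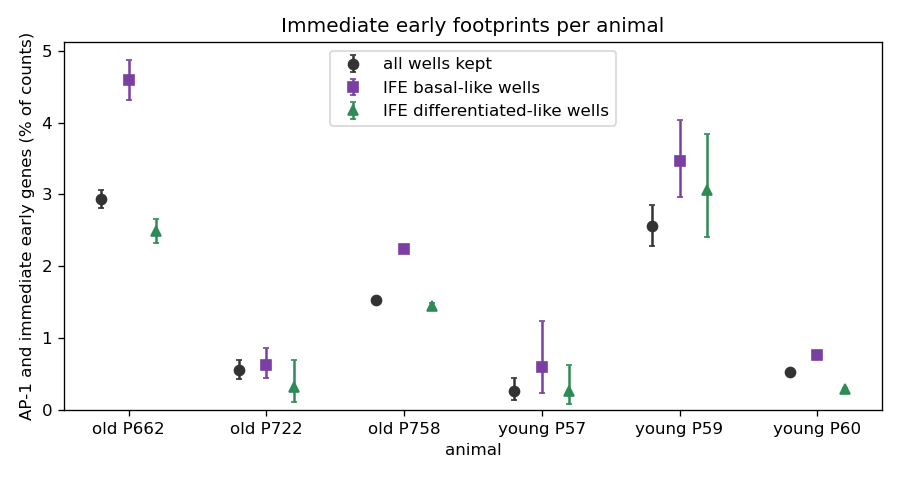
Share of counts in AP-1 and immediate early genes (y axis, % of counts) for each of the 6 animals (x axis), over all kept wells and within basal-like and differentiated-like wells. Points are shares and bars their 95% binomial intervals, and over all wells young P59 at 2.55% lies above old P722 at 0.551% and old P758 at 1.53%.

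Clustering of the 1906 wells gave 14 clusters, of which 11 could be named from the fixed markers. Basal-like cells of the interfollicular epidermis made up 42.5 ± 3.59% of the wells of old and 36.1 ± 11.7% of young animals (SD, n = 3 each, exact permutation p = 0.5). Over all wells, without a minimum count, a basal cluster stayed unnamed and the shares were 18.9 ± 10.1% and 18.9 ± 1.34%. Differentiated-like cells made up 17.9 ± 4.73% and 17.1 ± 6.89% (exact permutation p = 1). Outer bulge-like cells of the hair follicle were seen in all 3 old animals, at 5.51 ± 2.22%, and among young animals in P60 alone, at a mean of 1.80 ± 3.12% (exact permutation p = 0.3). Proliferating-like cells made up 2.17 ± 1.02% in old and 4.99 ± 2.81% in young animals (exact permutation p = 0.3), a difference of -2.82 percentage points that was -1.47 without P57 and -4.28 without P59. Sebaceous-like cells made up 1.54 ± 1.08% and 8.76 ± 12.4% (exact permutation p = 0.5), the latter set by 3 of the 13 wells of P57. T cell-like wells were found in P758 (19) and P60 (26), and Langerhans-like wells in P758 (3) and P60 (9), each with an exact permutation p of 1. Over all wells the Langerhans name also went to a cluster with no marker of that list among its leading genes, which gave 8.40 ± 3.25% in old and 13.1 ± 10.3% in young animals. Wells of the unnamed clusters 1, 5 and 8 made up 29.3 ± 3.60% and 30.1 ± 6.48%. Where a class had no wells in an animal, neither its absence nor a low share is excluded. At the lower clustering resolution of 0.5 differentiated-like wells made up 25.9 ± 2.54% in old and 21.2 ± 3.10% in young animals, with all 3 old above all 3 young (exact permutation p = 0.1, the smallest possible). The bulge difference turned to -4.72 percentage points on values not centred per plate and to -7.40 over wells with at least 500 counts. Each plate was taken as of 1 animal, so centring per plate can also remove differences in cell mix between animals. Without centring basal-like wells made up 38.7 ± 6.80% in old and 27.1 ± 24.6% in young animals, with 0% in P57 (exact permutation p = 0.7).

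No class had 10 cells in each of the 6 animals, as had been planned, so classes were tested without P57, with at least 5 cells in each of the other 5 animals. This was chosen after the data were seen. In differentiated-like cells edgeR called 8 of 740 genes. Cyp51, a demethylase of cholesterol synthesis, had 588 CPM in P662 and 414 CPM in P758, from 19 and 116 counts, and 113 CPM in P60, from 49 counts. P722 had 1 count, of 1888, and P59 had 0 of 2381, which allows up to 1260 CPM, so that the difference was not measured in these animals. The fitted log2 difference of Cyp51 was 1.97 (SE 0.473, edgeR adjusted p = 0.00460). Without P662, P722 or P59 its log2 difference was 1.73, 2.06 and 1.85, but the adjusted p was 1.00, 0.232 and 1.00. Without P60 it did not pass either, at 0.645, and without P758 the gene was not tested. The others called higher were the nuclear receptor Nr4a1 at 4.68, Ifrd1 at 3.69, the AP-1 subunit Fosl1 at 3.63, the matricellular protein Ccn1 at 3.54, Ccnl1 at 2.51 and the transcription factor Ovol1 at 2.01. Adh7, an alcohol dehydrogenase, was called lower at -1.73. For 6 of the 8 the plain means per age went against the fitted difference, for example 450 CPM in old and 1060 CPM in young animals for Ifrd1, where P59 had 2100 CPM, from 5 counts, and P60 20.8 CPM. Ifrd1, Ovol1 and Fosl1 also lead cluster 10, 1 of the 2 clusters of this class, which held 18 cells of P662, 0 of P722, 34 of P758, 3 of P59 and 2 of P60. Cluster 4 held the other 27, 5, 78, 6 and 92. Without the clusters led by immediate early genes, 1 of 501 genes was called, Cyp51, at a log2 difference of 2.17 (SE 0.464, edgeR adjusted p = 0.0262). DESeq2 called 0 of the 740, with 1 at an unadjusted p under 0.05 against 33 for edgeR. The count was 2 without P662, 10 without P722, 0 without P758, 10 without P59 and 0 without P60. Ccn1 and Fosl1 passed without P662, without P722 and without P59. Leaving out P59 or P60 leaves a lone young animal, assumed to vary like the others. Nr4a1 and Ifrd1 also passed without P722. The count was 0 when clusters were made on values not centred per plate. In GRCm38 Cyp51 lies on chromosome 5 from 4080674 to 4104697.

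In differentiated-like cells camera called 3 lists. All 16 AP-1 and immediate early genes were positive, with a median of 1.73 (adjusted p = 2.27e-15, and adjusted p = 0.929 with an estimated correlation), and 8 passed adjusted over the list alone. The plain shares do not follow this fit. In these wells the list took 2.49, 0.318 and 1.45% of counts in P662, P722 and P758, and 3.07% in young P59, the highest of the 5, beside 0.287% in P60. Of 10 lipid and cholesterol synthesis genes 7 were positive (adjusted p = 0.00409, and adjusted p = 0.929 with an estimated correlation), and 3 passed adjusted over the list alone. All 4 mitochondrially encoded genes were positive, with a median of 0.75 (adjusted p = 0.0277, and adjusted p = 0.929 with an estimated correlation). Without the clusters led by immediate early genes the lipid list had 7 of 8 positive genes (adjusted p = 0.000832) and the AP-1 list 12 of 12 (adjusted p = 0.00298), each with an adjusted p = 0.962 with an estimated correlation. The other 13 lists had an adjusted p between 0.350 and 0.822. Among them the median and the test differed in sign for keratins, antigen presentation and antioxidant genes.

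In basal-like cells Cxcl14 had 302 ± 61.6 CPM in the 3 old and 787 ± 188 CPM in the 2 young animals, a log2 difference of -1.51 (SE 0.360). It is also a leading gene of cluster 2, a basal-like cluster. Krt1 had a fitted log2 difference of 1.61, the co-chaperone Dnajb1 one of 1.36 and Atp5b one of -0.82. The unannotated 6430548M08Rik, at 1.09, leads an unnamed cluster of shallow wells. None of these passed. edgeR called 0 of 354 genes, with 7 at an unadjusted p under 0.05, and DESeq2 called 0, with 2. The count was 5 without P662, 4 without P722 and 10 without P59, which leaves P60 as the lone young animal, assumed to vary like the others. It was 29 without a filter on low counts and 12 with a mean of at least 20 CPM. The oxidative phosphorylation list, with 3 of its 74 genes tested, fell in basal-like cells. All 3 were negative, with a median of -0.75 (camera adjusted p = 0.0159, and adjusted p = 0.946 with an estimated correlation). The other 15 lists had an adjusted p between 0.263 and 0.908, with AP-1 genes at 0.385, and for cytokines and glycolysis the median and the test differed in sign. Adjusted over the list alone, 1 cytokine and 1 keratin passed. Of the basal-like clusters, cluster 7 is led by immediate early genes such as Nr4a1, Atf3 and Fos. Cluster 0, named at a score of 0.355, is led by mt-Nd1. Cluster 7 held 46 of the cells of P662, 1 of P722, 96 of P758, 8 of P59 and 67 of P60.

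The age difference itself was compared between differentiated-like and basal-like cells, with the animal as a block. Zfp750, a regulator of epidermal differentiation, had the smallest p, with a difference of -2.80 between the log2 changes of the 2 classes (SE 0.898). Notch3 had -1.79, while Ifrd1 had 1.66 and Nr4a1 1.69. These genes are named as not passing. edgeR called 0 of 986 genes, with 23 at an unadjusted p under 0.05, and DESeq2 called 0, with 6. On clusters from values not centred per plate edgeR called 1.

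Ribosomal protein genes took 0.539 ± 0.0707% of counts in old and 0.501 ± 0.143% in young animals (SD, n = 3 each, exact permutation p = 0.8). These genes share reads with many pseudogene copies and are uncertain. Mitochondrially encoded genes took 0.424 ± 0.0260% and 0.369 ± 0.181% (exact permutation p = 0.7).

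P758 and P60 held most of the counts, and their plates allow genes to be described that the shallow animals cannot measure. This comparison is of 1 old with 1 young animal, so there is no test, and it was added after the depths were seen. Cornified envelope genes stood higher in P758, with all 13 measured members higher and a median log2 ratio of 2.30 (percentile 100 of 10000 random lists matched on level). Filaggrin, Flg, had 628 CPM (95% Poisson interval 577 to 682) in P758 and 1.26 CPM (0.259 to 3.68) in P60, a 499-fold ratio (170 to 2427) with 99.1% of its counts in P758 in 3 wells. Loricrin, Lor, was 19.7-fold higher, with 96.8% of its counts in P758 in 3 wells, and Cdsn, a corneodesmosomal protein, 45.2-fold, with all of them in 2 wells. A few wells thus carried these genes. Within differentiated-like wells the cornified list had a median of -0.75, with 2 of 5 members higher. Over all wells all 24 lipid and cholesterol synthesis genes were higher, with a median of 0.61, and 20 of 21 AP-1 genes, with a median of 1.41. As shares of counts, other young animals stood above P758. Lipid genes took 1.19% in P57 and 0.542% in P59, beside 0.513% in P758 and 0.327% in P60. AP-1 genes took 2.55% in P59 and 0.268% in P57, beside 1.53% in P758. Cornified genes took 2.28% in P57 and 0.808% in P59, beside 1.62% in P758. Keratins had a median of 0.50, mitochondrially encoded genes 0.48 with 7 of 7 higher, and interferon response genes 0.54 with 5 of 7 higher. Mitochondrially encoded genes took 0.319 and 0.546% of counts on the plates of P758, beside 0.286 to 0.430% on those of P60. They took 0.566% in P59 and 0.210% in P57, beside 0.454% in P758. Keratins took 6.97% in P59 and 9.39% in P57, beside 8.65% in P758. Within differentiated-like wells the keratin median was -0.34, with 3 of 9 higher, and within basal-like wells 0.42, with 7 of 10 higher.

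Other groups stood lower in P758. Of 17 histone and cell cycle genes 1 was higher, and their median was -0.70. Within basal-like wells 4 of 10 were higher, with a median of -0.13. Proliferating-like wells made up 2.87% in P758 and 5.20% in P60, and their part in the lower values was not tested. The histone gene H4c12 had 2 counts in P758 and a ratio of P758 to P60 of 0.0818 (0.00970 to 0.308). The mitotic kinase Pbk was 5.58-fold lower and Ube2c, a ubiquitin-conjugating enzyme of mitosis, 4.80-fold. Hemidesmosome and basement membrane genes had a median of -0.44, extracellular matrix genes -0.35, antigen presentation genes -0.35 and nuclear-encoded oxidative phosphorylation genes -0.26, with 14 of 66 of the last higher. Fibronectin, Fn1, was 11.7-fold lower, with 43.2% of its counts in P60 in 3 wells. Angptl4, an inhibitor of lipoprotein lipase and a leading gene of the sebaceous-like cluster, was 10.7-fold lower, with 52.6% in 3 wells. Myoc, a leading gene of the outer bulge-like cluster, had 0 counts in P758 and 114 in P60, at least 14.3-fold lower against a floor of 3 counts, with 86.8% of its counts in 3 wells. Dct, an enzyme of melanin synthesis, had 0 counts in P758 and 69 in P60, at least 8.65-fold lower, with its counts in 5 wells. Of 8057 genes with enough counts 2599 (32.3%) had the 2 plates of P758 apart from the 3 of P60, and 1501 of these were lower in P758. Exchangeable plates would give 20%, but these plates come from 2 animals, so the excess does not bear on age.

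Within basal-like wells of the same 2 animals Krt6a and Krt16, keratins of stressed and hyperproliferative epidermis, were 88.9-fold (23.6 to 751) and 10.7-fold (5.55 to 22.2) higher in P758, with 88.5% and 95.5% of their counts in P758 in 3 wells. The immediate early genes Btg2 and Atf3 were 6.63-fold and 6.18-fold higher. Fn1 had 2 counts in P758 and a ratio of P758 to P60 of 0.119 (0.0140 to 0.454), with 55.1% of its counts in P60 in 3 wells. The natriuretic peptide receptor Npr3 was 6.86-fold lower, the basement membrane collagen Col4a1 5.57-fold and the aminopeptidase Anpep 4.37-fold. Within differentiated-like wells Krt15 was 2.91-fold, the laminin subunit Lamb3 3.72-fold and Adh7 3.36-fold lower. In that class 34 of the 112 cells of P758 and 2 of the 94 of P60 belonged to the cluster led by immediate early genes, and the AP-1 list had a median of 2.45.

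**Figure D2:**
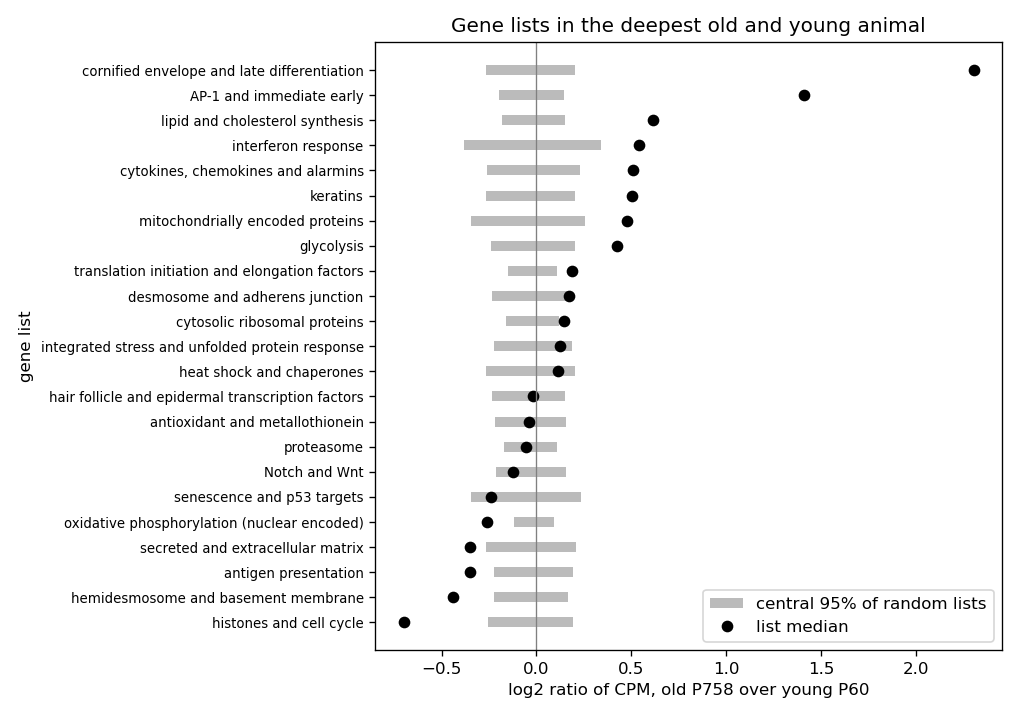
Median log2 ratio of old P758 over young P60 (x axis, log2 of CPM ratios) for each gene list (y axis) over all kept wells. Points are list medians and grey bars the central 95% of random lists matched on level, and the medians run from -0.70 for histones and cell cycle to 2.30 for the cornified envelope.

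A plate of Sca-1-negative cells was meant to hold cells other than stem cells. Its 52 kept wells came from a young and an old animal, which were not told apart here, and there is no test. Ly6a, the gene for Sca-1, had 0 of 17377 counts, which allows up to 173 CPM, while the 6 animals ranged from 0 to 388 CPM. Major histocompatibility class II genes, which antigen-presenting cells such as Langerhans cells express, stood above the range of the animals. Cd74 had 4431 CPM (95% Poisson interval 3497 to 5538) with counts in 13 wells, beside 0 to 194 CPM in the animals. H2-Ab1 had 2590 CPM beside at most 60.8 CPM, and H2-Eb1 2187 CPM beside at most 80.8 CPM. The Langerhans list had a median log2 ratio of 4.08 over the mean of the animals (percentile 100). In GRCm38 Ly6a lies on chromosome 15 from 74994877 to 74998031 and Cd74 on chromosome 18 from 60803849 to 60812652.

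Several keratinocyte genes stood lower on that plate, but not all. Krt14 had 1266 CPM beside 1721 to 11883 CPM in the animals, though its interval of 793 to 1917 CPM reaches the lowest of them, and Krt5 had 3568 CPM beside 4971 to 27316 CPM. Krt1 had 633 CPM beside 5891 to 16712 CPM and Krt10 had 4546 CPM beside 14236 to 32314 CPM. Within the animals' ranges lay Col17a1 at 3280 CPM (3059 to 7641 in the animals) and Krt15 at 5582 CPM (4649 to 17455). So did Sbsn at 921 CPM (776 to 3633) and Dmkn at 863 CPM (808 to 1945). The basal list had a median of -1.92 (percentile 0) and the differentiated list -1.07 (percentile 0.34). The sebaceous list had -1.93, but took 0.0230% of counts beside 0.0233 to 0.516% in the animals, the highest being P57. The granular list had -1.23 (percentile 5.43) and the proliferating list lay at percentile 0.68. They took 0.0230% and 0.0633% of counts, within the animals' ranges of 0.00457 to 0.134% and 0.0466 to 0.313%. Upper hair follicle genes had a median of 0.81 (percentile 94.3), within the central range of random lists matched on level. The median was -0.12 as a mean over wells. These genes took 1.61% of counts, within the animals' range of 0.192 to 2.25%. Krt79 had 7078 CPM, below the 11175 CPM of P722. Cst6 had 4316 CPM, with counts in 5 wells, beside at most 2639 CPM in the animals. T cell genes had 0.81, with Ptprc at 691 CPM, fibroblast genes 0.96, with Vim at 1036 CPM, and outer bulge genes 0.67, with Postn at 3223 CPM. The T cell, fibroblast and outer bulge medians lay within the central range of random lists matched on level. As means over wells the first and second were higher and the outer bulge median lower, again within that range. Over all wells the T cell median lay above it. Cd3g and Nkg7 of the T cell list and Sparc and Col1a2 of the fibroblast list lay at or below the floor of 3 counts. AP-1 genes had -0.02. Mitochondrially encoded genes took 1.20% of the plate's counts beside 0.210 to 0.566% in the animals. Lists for inner bulge, melanocyte, Merkel, macrophage, endothelial, muscle, fat and red blood cells had too few measured members for a median.

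**Figure D3:**
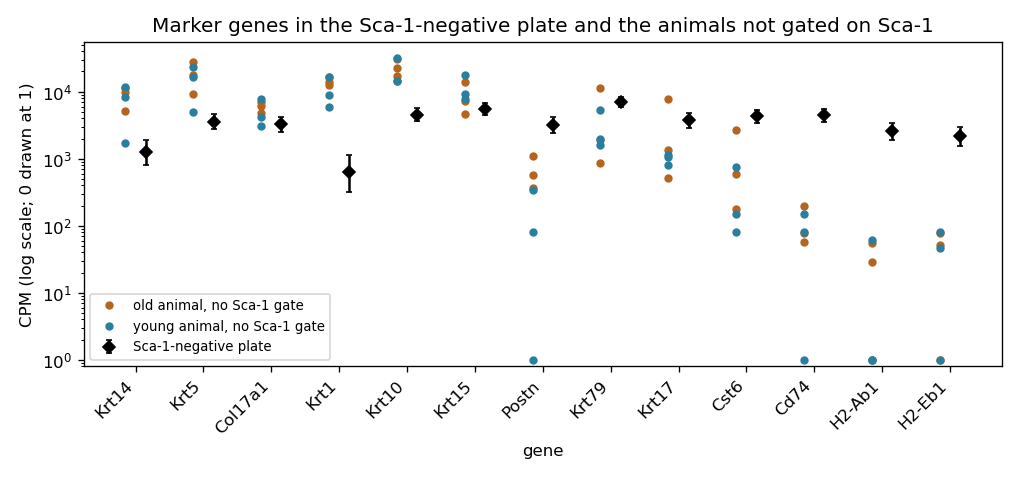
CPM (y axis, log scale, with 0 drawn at 1) of 13 marker genes (x axis) in each of the 6 animals not gated on Sca-1 (circles) and on the Sca-1-negative plate (diamonds, with 95% Poisson intervals). Cd74 at 4431 CPM and H2-Ab1 at 2590 CPM lie above all 6 animals, and Krt1 at 633 CPM lies below them.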

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

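The tests of plates and of age as sources of the AP-1 differences, and the test on genes called without a filter, were chosen after the values they explain were seen. Of 32 values examined within an age, 5 stood far from the rest. Chance marks about 1 in 20 groups in this way if plates are independent and alike. These plates are not, since some share an animal and their depths differ, so that rate is only a rough guide. Fos and Junb belong to the AP-1 list, so their flags and that of the list are not separate.

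Young plate 8, the single plate of P59, stood far above the other young plates, with AP-1 and immediate early genes at 2.55% of counts and the next plate at 0.596%. The same plate had Fos at 2991 CPM, with the next at 744 CPM, and Junb at 2263 CPM. On young plate 10, the single plate of P57, Cdkn1a had 574 CPM with the next plate at 162 CPM, where 1 count is worth 191 CPM. Ribosomal protein genes took 0.458% of counts on old plate 12, with the next plate at 0.559%. The nuclease test plate, of the same postnatal day as P758 and in no comparison, had mitochondrially encoded genes at 1.26% of counts (1.20 to 1.33), above 0.566% on the highest plate without a Sca-1 gate. Its ribosomal protein genes took 0.965% (0.912 to 1.02), with 0.622% on the highest of those plates.

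AP-1 and immediate early genes differed between animals of one age, with P59 over P60 at a log2 ratio of 2.27, a pair chosen after its values were seen. A different mix of cells is argued against by basal-like wells alone, where the ratio was 2.17 (1.94 to 2.40). A few extreme wells are argued against by the ratio of 2.40 (2.22 to 2.58) without the 10% of wells with the highest share, and depth by a 4.23-fold ratio (3.61 to 4.96) to the P60 wells of 100 to 500 counts. The comparison of the ages, with an exact permutation p of 0.5, decides nothing about a gap within an age, and no biological explanation was tested. Plates of one animal differed by at most 0.54 and animals of one age by up to 3.25 on the log2 scale, but plate and animal cannot be told apart for P59 and P57, which have 1 plate each, and handling of the tissue may differ and was not tested.

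The genes leading unnamed cluster 8, such as 6430548M08Rik, Acy1 and Vav1, may be background that does not scale with the RNA of a well. The deepest and the shallowest wells of a plate were taken as the upper and lower 25% by total. Between them the mean count of these genes had a ratio of 1.11 (median over the 5 plates of P758 and P60). Total counts had a median ratio of 12.9. The genes were picked for standing high, relative to other genes, in a cluster of shallow wells of the same data. That choice favours a low ratio, so the ratio cannot decide whether they are background. A cell class of its own is argued against in that only 19.4% of these genes' counts lay in the cluster, which holds 12.7% of the wells but 2.71% of all counts, so that they stand high there relative to other genes. Their mean count per well was 8.23 in P758 and 8.01 in P60, beside at most 0.824 in the other animals, and the source of the difference was not tested.

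Of the 111 genes called without a filter on low counts, 84.7% had 0 counts in the shallow animals of the lower age, as a lack of depth there could give. None of them was among the genes of the filtered test, and 75 were called higher and 36 lower in old animals. No biological explanation was tested for them.

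For the whole epidermis the real split of the 6 animals called 0 genes and the highest of the others 16, and 10 of the 10 splits called as many as the real one. The split that called 16 sets P662, P758 and P59 against the rest, and 11 of the 16 genes belong to the AP-1 and immediate early list, counted after the split was seen. This points to a structure of the samples, of which no cause was tested here. For gene lists the real split called 3 and the highest other 5, and 6 of the 10 splits called as many. With 10 splits a share under 0.05 cannot be reached.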

How the results depend on the processing

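The counts without P57 in single classes, over wells of at least 500 counts and without clusters led by immediate early genes were chosen after the data were seen, as were other clusterings for the shares and the interaction. Of the settings tried, 307 for single genes and 154 for other results counted as unchanged, 13 and 14 reversed, 23 were weaker, 11 stronger and 4 moved. For log2 differences of single genes and for differences in shares between the ages, unchanged means the same sign only, whatever the size. The basal-like share difference thus counted as unchanged at 6.42 percentage points in the main setting and 0.0613 over all wells. Numbers of called genes could also differ. In differentiated-like cells 8, and 10 without P722, counted as unchanged. Genes called across the whole epidermis numbered 111 without a filter on low counts and 45 at a mean of at least 20 CPM, and in basal-like cells 29 and 12. Leaving out single animals gave 0 to 10 in basal-like cells. In differentiated-like cells the 8 became 0 with DESeq2, 16 without a filter, 13 at 20 CPM, 0 without centring per plate, 1 at resolution 0.5, 1 at resolution 2, 1 without clusters led by immediate early genes and 0 to 10 without single animals. The interaction gave 1 without centring. Called lists were 0 with an estimated correlation, 0 with fry and 0 to 5 without single animals. The log2 difference of Krt14 was -0.0705 after thinning and -0.12 to 0.75 without single animals. For Krt5 it was -0.0623 and -0.14 to 0.67. For Krt10 it was -0.00829 over wells of at least 500 counts and -0.0671 to 0.79 without single animals, and for Col17a1 -0.0799 to 0.69. It ran from 0.50 to 1.13 for Dmkn, 0.18 to 1.04 for Krt1 and -0.79 to -0.02 for Krt15. Without single animals the difference in shares, in percentage points, ran from -0.0690 to 11.3 for basal-like, -3.04 to 3.71 for differentiated-like, -0.306 to 0.159 for Langerhans-like, -0.883 to 1.01 for T cell-like, -4.28 to -1.47 for proliferating-like, -11.0 to -0.0631 for sebaceous-like, 2.51 to 5.51 for outer bulge-like and -4.30 to 2.10 for unnamed wells. It ran from -0.0415 to 0.0976 for ribosomal protein and -0.0244 to 0.153 for mitochondrially encoded genes. Over all wells it was 0.0613 for basal-like and -4.70 for Langerhans-like wells. The differentiated-like difference was 4.65 at resolution 0.5. The T cell-like one was -0.137 over wells of at least 500 counts, and the outer bulge-like one -7.40 there and -4.72 without centring. As means over wells, lists on the Sca-1-negative plate took 1.32% (basal), 0.523% (differentiated), 0.665% (upper hair follicle) and 1.27% (outer bulge) of counts. Fewer genes or animals were tested under some of these, and beyond that the cause was not tested. A minimum of 2000 counts per well was not run, since P722, P57 and P59 had no such well, nor were basal-like cells and the interaction over all wells, where P722 had 3 basal-like cells. No paired analysis was possible because old and young animals share no plate number or other link. Depth limits P57, P59 and P722, where 1 count in P57 is worth 191 CPM.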

Other observations

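Further gene groups were compared between old P758 and young P60, with 1 animal per age and no test, a comparison chosen after the depths were seen. All 7 measured mitochondrially encoded genes were higher in P758 in basal-like wells, with a median log2 ratio of 0.58, and all 6 in differentiated-like wells, with 1.13. Over all wells they took 0.319 and 0.546% of counts on the plates of P758, beside 0.286 to 0.430% on those of P60. Plates were not set apart within basal-like or differentiated-like wells for these shares. Nuclear-encoded oxidative phosphorylation genes had medians of -0.32 and -0.17 in these classes, with 16 of 55 and 15 of 39 members higher. Lipid and cholesterol synthesis genes had medians of 0.18 in basal-like and 0.63 in differentiated-like wells. Extracellular matrix genes had -0.45 in basal-like and -0.08 in differentiated-like wells, and hemidesmosome genes had -0.22 and -0.41. None of the 10 antigen presentation genes measured in basal-like wells was higher, and their median was -0.39. In differentiated-like wells 3 of 8 were higher, with a median of -0.08.

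Outer bulge-like wells numbered 32 in P758 and 53 in P60. Keratins there had a median of -0.71, with 2 of 7 higher, and mitochondrially encoded genes -0.60, with 0 of 4 higher. S100a6, a calcium-binding protein, was 2.04-fold higher in P758 (1.45 to 2.86), with 57.1% of its counts in P758 in 3 wells. Sbsn, a protein of suprabasal cells, had a ratio of P758 to P60 of 0.327 (0.136 to 0.681), with 37.7% of its counts in P60 in 3 wells. These 2 genes were chosen after their values were seen, among the 10 largest ratios in each direction, and leading genes of the cluster were left out.

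The nuclease test plate had 242 wells with 73 to 2269 counts and a median of 358.5. Against the plates of P758, of the same postnatal day and not known to be the same animal, its cornified envelope genes had a median log2 ratio of -2.52, with 1 of 11 higher. In P758 such genes can rest on few wells, as Flg does, with 99.1% of its counts in 3 wells. Mitochondrially encoded genes had a median of 1.41 and ribosomal protein genes 0.68. Lipid and cholesterol synthesis genes had -0.59, proteasome genes -0.44 and AP-1 genes 0.28. Which well received which nuclease was not used here.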
